A study of Rattus norvegicus with 6 samples.

How the data were processed

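Bulk RNA sequencing data of 6 libraries of mesenchymal stem cells from rat nasal mucosa were analysed. Per the labels, 3 libraries came from cells named EMSC and 3 from cells named NPS-EMSC, and the series title describes stem cells made to overexpress neuropeptide S. The labels give SD as the genotype and call the cells primary. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were built with a VAHTS Universal V6 kit. The submitters' processing notes name fastp, HISAT2, HTSeq, StringTie, DESeq and R 3.2.0, with no role or order for any of them. The genome build, the gene annotation, the strand setting and the other tool versions are not given in the sources used here, so no coordinates are printed.

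The authors deposited a table of raw read counts per gene with 1 column per library, and the values were whole numbers. The authors also deposited an FPKM table of the same 20653 genes. Dividing the deposited counts by the deposited FPKM values and the column total gave 1 fixed length per gene in all 6 libraries, to within 0.1 percent, for all 20653 genes. The FPKM table is therefore the count table rescaled and not a separate measurement. Every row of the count table held at least 1 read over the 6 libraries, and Npsr1, the neuropeptide S receptor gene, had no row in either table. Of the gene symbols, 18153 were found as current symbols in the RefSeq gene table of rat assembly GRCr8 and 390 as synonyms only. That table was used for names alone.

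Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest), after TMM normalisation and the filterByExpr filter at its default minimum count of 10 and minimum total of 15. This left 14505 tested genes. The 6148 untested genes held between 0.0337% and 0.0393% of a library's reads. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and every adjusted p printed for a gene comes from this test. Log2 fold changes are NPS-EMSC minus EMSC, with a prior count of 2, and are given with a standard error (SE) on the log2 scale. This SE was not fitted directly but is the absolute log2 fold change divided by the square root of the F value of the test. The prior count pulls the fitted folds of genes with few reads in 1 group towards 0, and their SE with them, so for such genes the SE is only a rough guide. CPM values are read counts scaled by the TMM-scaled library total and are given as mean ± SD (n = 3).

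Before the data were examined, 34 gene lists were fixed, and 31 of them had at least 5 tested members. These were tested with camera of limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 31 lists. Camera compares a list with all other genes. It was repeated with the correlation estimated from the data, and fry was run beside it. Fry asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Member counts are given over all genes tested and adjusted over the list alone.

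Genes were named by a rule that was also fixed before the data were examined. It takes Nps and Npsr1, the 10 genes with the largest increase and the 10 with the largest decrease, up to 4 members of each list that passed camera and of the PI3K list, and up to 2 members of every other list with a called member. Members were taken by smallest p. The largest changes were chosen among called genes without overlap between the groups, with a mean of at least 5 CPM in the higher group and without a clone or locus name. Genes outside this rule whose values are given were chosen after these were seen and are marked as such in the text. Some of the genes chosen are not reported here.

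The processing was varied with RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 1 CPM in at least 3 libraries, and limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with an FPKM of at least 0.5 in at least 3 libraries. The remaining ones were log2(FPKM + 1) without a filter, the replicate number as a block, an adjusted p under 0.01, and leaving out each library in turn.

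The procedure was tested on simulated counts made from the real means and library totals, in which 200 of 14312 genes tested in that step carried a known change. The changed genes were drawn from those with a mean of at least 1 CPM, and each gene had the spread of the trend at its level. The procedure recovered 54% of the 1.2-fold changes, 80% of the 1.5-fold changes, 98% of the 2-fold changes and 100% of the 4-fold changes, with 50 genes of each size. These shares do not cover tested genes under 1 CPM or genes with a spread off the trend. Of the 14112 unchanged genes, 7 were called. A simulated list shifted by 0.5 on the log2 scale passed camera, with adjusted p = 5.77e-04 with an estimated correlation, and none of 29 lists without a shifted gene passed (0 of 29). The simulated genes were drawn independently of each other, so this does not test camera where genes of a list vary together. In the real data the estimated correlation reached 0.382 in the cell cycle list, for example.

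Library totals lay between 39082245 and 40261205 counted reads. Between libraries of 1 group the chi-square per degree of freedom over genes was 5.08 to 12.6, so no library repeated another within sampling noise. The labels do not say whether the 3 libraries of a group came from separate animals or cultures, and p-values then measure the spread between these libraries, which may be technical. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical genes may have been split between copies. Intervals and floors from counts cover counting error only.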

Results

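Transcript levels were measured by RNA sequencing in mesenchymal stem cells from the nasal mucosa of rats, in 3 libraries of cells named EMSC and 3 libraries of NPS-EMSC, the cells made to overexpress neuropeptide S. Neuropeptide S is a short secreted peptide that acts through a G protein-coupled receptor. The gene of that receptor, Npsr1, had no row among the deposited counts. Whether it had no reads or is missing for another reason is not known. The EMSC libraries held 39314098 to 40261205 counted reads and the NPS-EMSC libraries 39082245 to 39511976. On average 17538 genes had at least 1 read in an EMSC library and 17597 in an NPS-EMSC library. The comparison asks which transcripts differ between the NPS-EMSC and the EMSC libraries. The cell type labels do not say whether EMSC carried a control vector. Effects of gene delivery or of selection in culture cannot be told apart here from those of neuropeptide S. The series title names the PI3K/AKT/GSK3β pathway as the one of interest in a rat model of spinal cord injury.

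Nps, the gene of the neuropeptide S precursor, separated the groups. It had 93566, 77014 and 85916 reads in the 3 NPS-EMSC libraries and 0, 0 and 10 reads in the 3 EMSC libraries. Its level was 2214 ± 226 CPM in NPS-EMSC (SD, n = 3), or 0.218% of all counted reads, against 0.0835 ± 0.145 CPM in EMSC. The fitted log2 fold change was 14.02 (SE 0.31, adjusted p = 7.62e-07). All Nps reads of the EMSC group lay in EMSC replicate 3. Without that library the EMSC group stood at 0, the fitted value was 15.41, and Nps was at least 60212-fold higher in NPS-EMSC against a floor of 3 counts over the 2 remaining libraries. With all libraries the fitted fold was 16664, so 60212 is no lower bound for the full comparison. The counts do not separate transgene from endogenous transcripts.

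Of 14505 genes tested, 8600 (59.3%) passed, 4314 of them higher and 4286 lower in NPS-EMSC. Most differences were small, with a median absolute log2 fold change of 0.52 among called genes. At a fitted change of at least 2-fold, 940 genes were higher and 1204 lower. In 9388 genes (64.7%) the 3 values of 1 group did not overlap the 3 of the other, where chance gives 10%. The biological coefficient of variation within groups was 0.0737.

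After Nps, the largest increase was in Cyp4b1, a cytochrome P450 gene, which rose from 0.0490 ± 0.0417 to 15.1 ± 1.01 CPM (SD, n = 3; log2 fold change 7.25, SE 0.25, adjusted p = 1.65e-18). Pln, which encodes phospholamban, the inhibitor of the calcium pump of muscle, rose from 0.263 ± 0.125 to 33.5 ± 2.06 CPM (log2 fold change 6.74, SE 0.17). Ednrb, an endothelin receptor gene, was the most abundant of the other top genes and rose from 2.36 ± 1.03 to 127 ± 9.55 CPM (log2 fold change 5.71, SE 0.25, adjusted p = 1.91e-05). Stac2, whose product binds voltage-gated calcium channels, rose by 6.60 on the log2 scale, Pex5l by 6.26 and the transcriptional coregulator gene Cited1 by 6.11. Dkk1, a secreted inhibitor of Wnt signalling, rose by 5.86 (SE 0.34). Serpina6, the corticosteroid-binding globulin gene, rose by 6.84 (SE 0.35). Its 4 EMSC reads all came from EMSC replicate 1, without which the fitted value was 7.55 and the gene was at least 255-fold higher against a floor of 3 counts over 2 libraries. Lypd1 had 1 read over the EMSC group and 621 over the NPS-EMSC group, a ratio of 651 (95% counting interval 116 to 25757).

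Among the largest decreases was that of Unc13c, a gene of synaptic vesicle priming, which fell from 33.6 ± 5.09 to 0.362 ± 0.186 CPM (SD, n = 3; log2 fold change -6.35, SE 0.20). Cyp1a1, the classical target of the aryl hydrocarbon receptor, fell from 29.4 ± 7.34 to 0.276 ± 0.122 CPM (log2 fold change -6.50, SE 0.25). Myom2, the gene of a sarcomeric M-band protein, fell with a log2 fold change of -6.32, the fatty acid transport gene Slc27a6 with -5.70 and the matrix protein gene Vit with -5.67. Abca13 and Iqgap2 had log2 fold changes of -5.12 and -5.06, and Comp, the cartilage oligomeric matrix protein gene, one of -5.01. Tgm5, a transglutaminase gene, had 677 reads over the EMSC group and 1 over the NPS-EMSC group, a ratio of 646 (95% counting interval 116 to 25542).

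**Figure D1:**
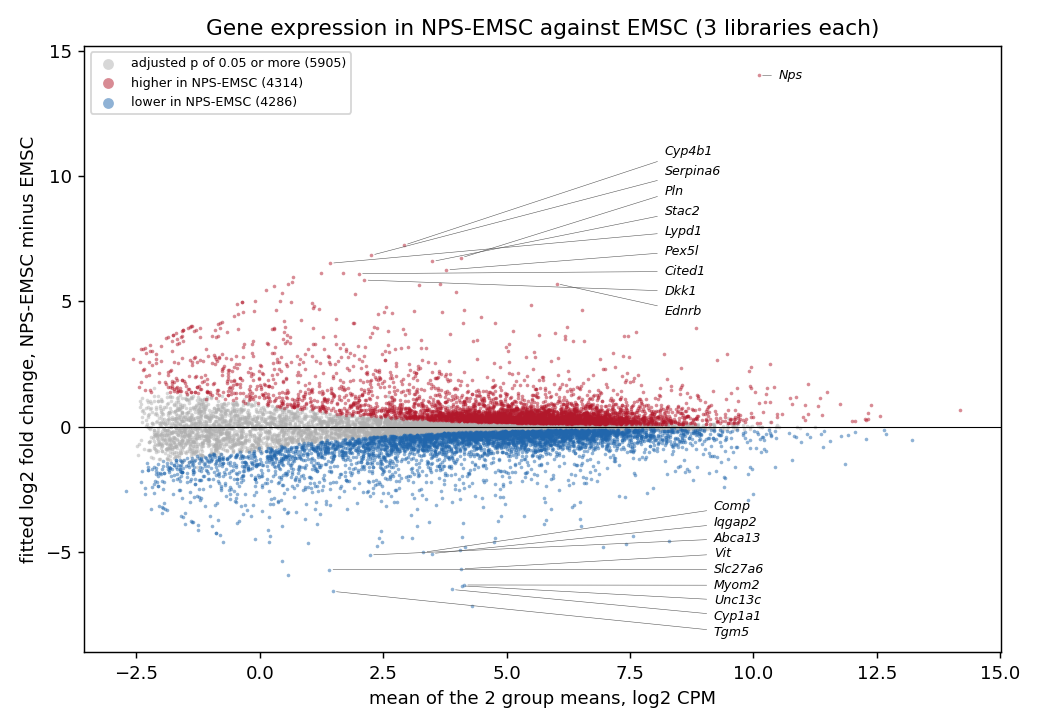
Fitted log2 fold change of each of the 14505 tested genes (vertical axis, NPS-EMSC minus EMSC) against the log2 of the mean of the 2 group CPM means (horizontal axis). Red points are the 4314 genes called higher and blue points the 4286 called lower, grey points were not called, and labels mark the genes among the largest increases and decreases that are named in the text, with Nps at 14.02.

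Smooth muscle genes rose together. Of the 13 tested members of the smooth muscle and myofibroblast list, 12 rose and none fell (0 lower), and the counts adjusted over the list alone were the same. Myh11, the smooth muscle myosin heavy chain gene, rose from 6.94 ± 0.764 to 177 ± 12.7 CPM (SD, n = 3; log2 fold change 4.67, SE 0.08, adjusted p = 9.75e-24). Acta2, smooth muscle actin, rose 5.20-fold to 1653 ± 43.9 CPM. The matricellular growth factor gene Ccn2 rose 3.23-fold to 3369 ± 155 CPM, and Myl9, a regulatory myosin light chain gene, rose 2.83-fold to 537 ± 6.79 CPM. The member that did not pass was the intermediate filament gene Des, at 0.586 ± 0.417 CPM in EMSC and 0.802 ± 0.321 CPM in NPS-EMSC (adjusted p = 0.484). The median log2 fold change of the list was 1.53 and it passed camera (adjusted p = 6.47e-11), but not with the correlation estimated from the data (adjusted p = 0.0539 with an estimated correlation). The estimated correlation was -0.0125, below the preset 0.01, so a higher correlation was not what lost this call. Actin genes are near-identical in sequence, and reads may have been split among Acta2, Acta1 and Actg2.

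Most p53 targets rose and most cell cycle genes fell. Among 20 tested members of the list of p53 targets and senescence genes, 16 rose and 4 fell, with the same counts adjusted over the list alone. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, rose from 77.2 ± 3.93 to 326 ± 17.0 CPM (SD, n = 3; log2 fold change 2.08, SE 0.05, adjusted p = 3.10e-21). Mdm2, the ubiquitin ligase gene that p53 induces, rose 2.74-fold, Ccng1 2.40-fold and Tp53inp1 2.23-fold. The 4 that fell were Cdkn1b, Cdkn2a, Cdkn2b and Sesn1, and the first 3 of these also encode cell cycle inhibitors. The list had a median log2 fold change of 0.91 and camera adjusted p = 3.13e-05 (adjusted p = 0.133 with an estimated correlation). In the cell cycle list, 24 of 33 tested members fell and 3 rose, also when adjusted over the list alone. Ccnb1, the mitotic cyclin B1, fell from 18.8 ± 2.14 to 8.19 ± 0.312 CPM (log2 fold change -1.19, SE 0.11, adjusted p = 1.27e-09). The replication helicase gene Mcm5, the topoisomerase gene Top2a and the mitotic checkpoint kinase gene Bub1 also fell, with log2 fold changes of -1.21, -1.18 and -0.97. The members that rose were Ccne1, Cdk1 and Cdt1. The median log2 fold change was -0.73 and camera gave adjusted p = 5.10e-05 (adjusted p = 0.551 with an estimated correlation). Cdk1, Ccne1, Cdt1, Cdkn1b, Cdkn2a, Cdkn2b, Sesn1 and Des lie outside the naming rule and were named after their values were seen, Des because it did not pass and the others because they went against the rest of their lists.

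Most neurotrophic factor genes rose, and most axon guidance genes fell. Of 16 tested neurotrophic factors, 11 rose, 1 fell and 4 did not pass, with the same counts adjusted over the list alone. Bdnf, brain-derived neurotrophic factor, rose from 22.7 ± 0.753 to 69.9 ± 3.35 CPM (SD, n = 3; log2 fold change 1.62, SE 0.06, adjusted p = 3.88e-17). Hgf, hepatocyte growth factor, rose 2.48-fold and Vegfa 2.21-fold. Ptn, pleiotrophin, was the member that fell, from 170 ± 17.0 to 40.5 ± 0.413 CPM (log2 fold change -2.07, SE 0.06). The list had a median of 0.86 and camera adjusted p = 0.00153 (adjusted p = 0.197 with an estimated correlation). Of 29 tested axon guidance genes, 22 fell and 6 rose, or 23 and 6 adjusted over the list alone. The semaphorin co-receptor genes Nrp1 and Nrp2 fell 3.65-fold and 3.22-fold, Nrp2 from 1541 ± 117 to 478 ± 6.53 CPM. The netrin receptor gene Unc5c fell from 45.9 ± 3.90 to 13.4 ± 0.283 CPM, and the secreted semaphorin gene Sema3d fell from 1030 ± 60.3 to 518 ± 10.8 CPM (log2 fold change -0.99, SE 0.05, adjusted p = 2.85e-15). The median of the list was -0.68 and camera gave adjusted p = 2.67e-06 (adjusted p = 0.328 with an estimated correlation).

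Surface markers used to define mesenchymal stem cells rose in 8 of 10 tested members and fell in 2, also when adjusted over the list alone. Thy1 (CD90) rose from 417 ± 8.15 to 1217 ± 34.0 CPM (SD, n = 3; log2 fold change 1.55, SE 0.05, adjusted p = 8.76e-20). Nt5e (CD73) rose 4.45-fold to 61.7 ± 2.90 CPM, and Mcam (CD146), a marker shared with pericytes and vascular smooth muscle, rose 12.9-fold from 1.06 ± 0.387 CPM. Vcam1 fell from 16.0 ± 0.515 to 2.72 ± 0.382 CPM. The median of the list was 0.64, with camera adjusted p = 0.00153 (adjusted p = 0.328 with an estimated correlation).

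Genes of the antioxidant and hypoxia responses were mostly higher. Of 17 NRF2 antioxidant genes, 14 rose and 1 fell, with the same counts adjusted over the list alone. Srxn1, sulfiredoxin, rose from 41.6 ± 2.02 to 174 ± 4.80 CPM (SD, n = 3; log2 fold change 2.06, SE 0.05, adjusted p = 4.31e-21), the aldo-keto reductase gene Akr1b8 rose 2.99-fold, Gstp1 2.58-fold and the thioredoxin reductase gene Txnrd1 2.13-fold. The median was 0.74 and camera gave adjusted p = 5.26e-07 (adjusted p = 0.328 with an estimated correlation). In the hypoxia and glycolysis list, 19 of 27 tested members rose and 1 fell, also when adjusted over the list alone. Pfkfb3, which encodes an enzyme that activates glycolysis, rose from 63.4 ± 4.80 to 283 ± 22.7 CPM (log2 fold change 2.16, SE 0.06), and Adm, adrenomedullin, rose 2.48-fold. Ndrg1 was the member that fell, from 157 ± 5.32 to 33.3 ± 2.48 CPM (log2 fold change -2.23, SE 0.06). This list had a median of 0.51 and camera adjusted p = 5.67e-06 (adjusted p = 0.359 with an estimated correlation).

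The list of the unfolded protein and integrated stress responses was split. Of 27 members 15 rose and 8 fell, or 15 and 9 adjusted over the list alone. Atf3, a stress-induced transcription factor, rose from 1.36 ± 0.131 to 10.9 ± 0.379 CPM (SD, n = 3; log2 fold change 2.97, SE 0.17, adjusted p = 7.21e-14). The cystine transporter gene Slc7a11 rose 3.63-fold, Ppp1r15a 2.03-fold and Atf4, the main transcription factor of the integrated stress response, 1.54-fold. Named after their values were seen, the genes of the endoplasmic reticulum protein disulfide isomerases Pdia4 and Pdia6 fell, with log2 fold changes of -0.51 and -0.55, and the chaperone gene Hspa5 had a log2 fold change of -0.10 (adjusted p = 0.0609). The median of the list was 0.29 and camera gave adjusted p = 0.0354 (adjusted p = 0.530 with an estimated correlation). This call was lost under the stricter filter (adjusted p = 0.0538), on log2(FPKM + 1) values (adjusted p = 0.0527) and without EMSC replicate 3 (adjusted p = 0.0546). Over the 12 alternatives that change the filter, the scaling, the unit, the block or the libraries, its adjusted p was 0.0146 to 0.0546.

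**Figure D2:**
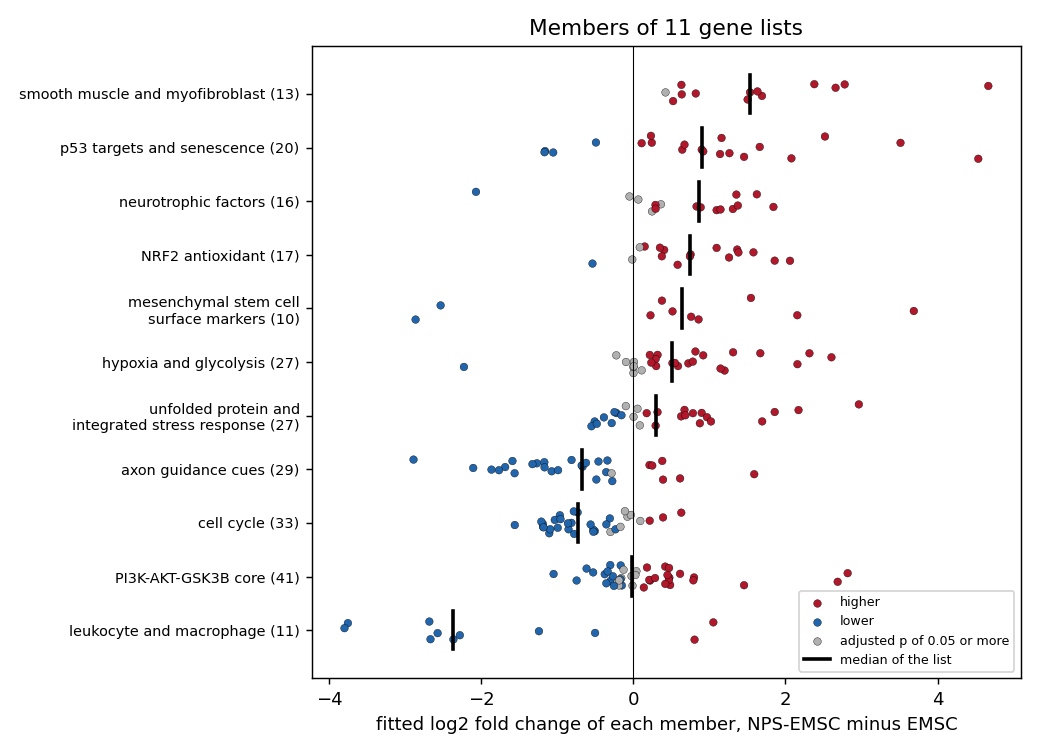
Fitted log2 fold change (horizontal axis, NPS-EMSC minus EMSC) of each tested member of 11 gene lists, with the number of tested members in brackets. Points are single genes, red where called higher, blue where called lower and grey where not called, vertical bars are list medians, and the upper 9 lists passed camera with the preset correlation, with medians from 1.53 for smooth muscle and myofibroblast genes to -0.73 for cell cycle genes.

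The genes of the PI3K, AKT and GSK3 pathway named in the series title changed in both directions. Of 41 tested members of the core list, 18 rose, 14 fell and 9 did not pass, or 18 and 15 adjusted over the list alone. The member with the smallest p was Mdm2, which is also on the p53 list and rose from 61.5 ± 1.74 to 169 ± 2.13 CPM (SD, n = 3; log2 fold change 1.46, SE 0.05, adjusted p = 9.00e-19). Pik3r1, the main regulatory subunit gene of PI3K, fell from 221 ± 16.7 to 144 ± 4.43 CPM (log2 fold change -0.62, SE 0.05), Inpp4b, a phosphoinositide phosphatase gene, fell from 31.7 ± 0.664 to 15.3 ± 2.03 CPM (log2 fold change -1.05, SE 0.09), and Ctnnb1, β-catenin, fell from 565 ± 16.1 to 391 ± 18.9 CPM (log2 fold change -0.53, SE 0.05). Named from the series title after their values were seen, Gsk3b rose by 0.21 (SE 0.05, adjusted p = 6.21e-04) and Gsk3a by 0.48, while Akt1 had a log2 fold change of -0.15 and Akt2 of -0.30. Taken as a list, the pathway did not stand apart from other genes, with a median log2 fold change of -0.0125, a mean of 0.17, and camera, which pointed upward, at adjusted p = 0.684 (adjusted p = 0.767 with an estimated correlation). Fry, which does not compare with other genes, pointed upward at adjusted p = 0.00489. Transcript levels do not measure the phosphorylation through which this pathway signals.

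**Figure D3:**
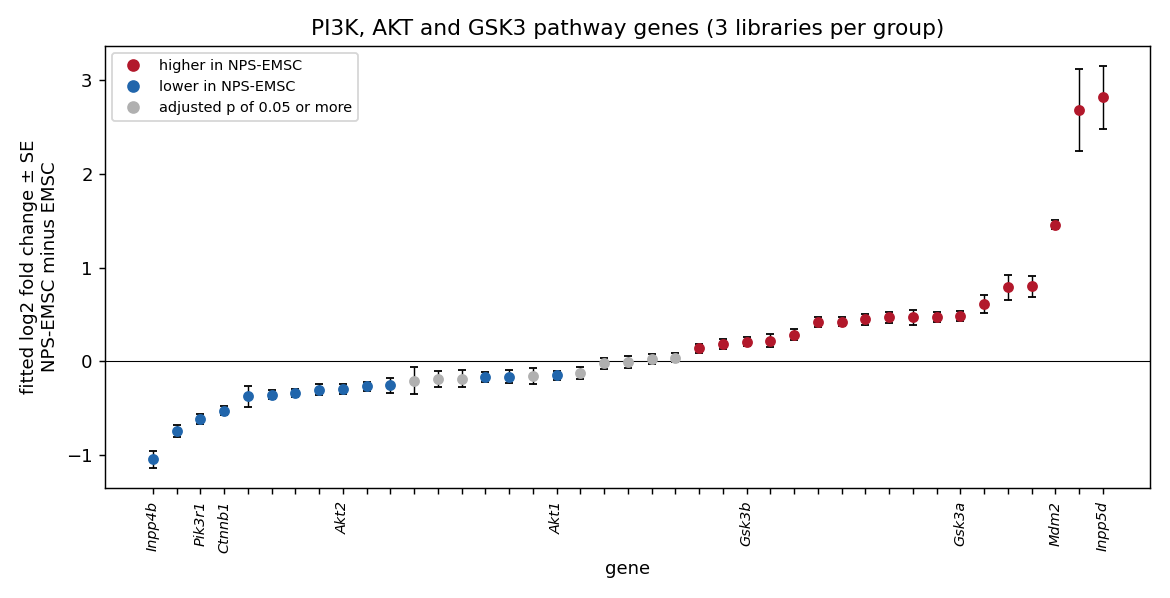
Fitted log2 fold change (vertical axis, NPS-EMSC minus EMSC) of the 41 tested genes of the PI3K, AKT and GSK3 list, in order of the change, with bars of 1 SE from 3 libraries per group. The 14 blue genes were called lower, the 18 red genes higher and the 9 grey genes were not called, the values ran from -1.05 for Inpp4b to 2.82 for Inpp5d, named after its value was seen, and labels mark the genes named here.

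Genes of BMP and TGF-β signalling were more often lower, without passing as a list. Of 25 tested members, 15 fell and 7 rose, with the same counts adjusted over the list alone. Id1 and Id2, direct targets of BMP signalling, fell 7.12-fold and 3.81-fold, Id1 from 95.0 ± 6.41 to 13.3 ± 1.58 CPM (SD, n = 3; log2 fold change -2.83, SE 0.08, adjusted p = 2.11e-19). The median was -0.35 and camera gave adjusted p = 0.0601 (adjusted p = 0.328 with an estimated correlation). Among 19 tested Wnt targets and modulators, 6 rose and 7 fell, the same adjusted over the list alone. The members with the smallest p were Sfrp2, a secreted Wnt modulator gene, which fell from 148 ± 15.0 to 16.9 ± 0.408 CPM, and the R-spondin receptor gene Lgr5, with a log2 fold change of -1.89 (SE 0.06). Dkk1 rose, as given above, and so did Nkd2, named after its values were seen, from 24.8 ± 3.35 to 308 ± 8.52 CPM (log2 fold change 3.63, SE 0.07). The Wnt list had a median of 0.04 and a mean of 0.12, camera pointed downward, and its adjusted p was 0.683.

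Matrix and adhesion genes moved in both directions. Of 27 collagen and fibrous matrix genes, 8 rose and 14 fell, or 9 and 14 adjusted over the list alone (median -0.13, camera adjusted p = 0.331). The small proteoglycan genes Dcn and Lum fell 3.07-fold and 2.54-fold, Lum from 2511 ± 151 to 988 ± 15.1 CPM (SD, n = 3). Of 27 tested integrin and laminin genes, 11 rose and 11 fell, also when adjusted over the list alone (median 0.12, camera adjusted p = 0.683). Itga7, the laminin receptor chain of muscle, rose from 1.29 ± 0.357 to 34.0 ± 0.262 CPM (log2 fold change 4.67, SE 0.13), and the collagen receptor gene Itga11 rose 3.40-fold. Among 17 tested metalloproteinases and inhibitors, 9 rose and 5 fell, the same adjusted over the list alone, with a median of 0.39, a mean of -0.08 and an upward camera test at adjusted p = 0.137. Mmp2, gelatinase A, rose 2.19-fold to 3590 ± 235 CPM and Adamts1 2.28-fold to 2576 ± 145 CPM.

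Several markers of other cell types differed between the groups. Of 11 tested leukocyte and macrophage genes, 9 fell and 2 rose, also when adjusted over the list alone. The lysozyme gene Lyz2 fell from 52.5 ± 7.71 to 3.84 ± 0.940 CPM (SD, n = 3; log2 fold change -3.76, SE 0.15, adjusted p = 2.78e-10), while Cd14 rose from 15.1 ± 2.43 to 31.4 ± 0.614 CPM. The median of this list was -2.37, with camera adjusted p = 0.0825 (adjusted p = 0.328 with an estimated correlation). Of 8 tested skeletal muscle genes, 5 rose and 1 fell, the same adjusted over the list alone (median 1.97, camera adjusted p = 0.155). The embryonic myosin gene Myh3 rose from 0.240 ± 0.115 to 5.59 ± 1.32 CPM and the skeletal actin gene Acta1 from 0.664 ± 0.234 to 6.05 ± 0.527 CPM. Of 14 nasal epithelium genes only Krt8 and Krt18 passed the filter and both rose, Krt18 to 5.98 ± 0.871 CPM and Krt8 to 5.75 ± 1.29 CPM. Among 6 tested endothelial genes, 1 rose, Egfl7, with a log2 fold change of 0.71 (SE 0.09), and Erg had a log2 fold change of -0.82 (adjusted p = 0.0553). The endothelial median was -0.15, the mean 0.02, and camera pointed upward at adjusted p = 0.684. Of 9 tested glial genes, 5 fell and 1 rose, the same adjusted over the list alone (median -0.42, camera adjusted p = 0.169), with S100b down from 13.2 ± 0.611 to 3.30 ± 0.269 CPM.

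Mitochondrially encoded transcripts took 3.55 ± 0.0766% of the reads in EMSC and 4.37 ± 0.0544% in NPS-EMSC (SD, n = 3). Of 13 tested mitochondrial genes, 3 rose and 2 fell, the same adjusted over the list alone (median 0.12, camera adjusted p = 0.491). COX1, a cytochrome c oxidase subunit gene, rose from 14302 ± 306 to 22712 ± 363 CPM (log2 fold change 0.67, SE 0.05), and CYTB, cytochrome b, rose 1.22-fold. The Y-linked genes Ddx3y and Eif2s3y, named after their values were seen, had 0 to 3 reads in each of the 6 libraries.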

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

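All alternatives were planned. The counts of genes higher and lower in NPS-EMSC stayed within 1.5 times of 4314 and 4286 under every alternative run, between 3492 and 4539 higher and between 3495 and 4662 lower. The share of calls that were higher ran from 45.4% to 51.2%, and no called gene was called with the opposite sign under any alternative. The counts of genes changed at least 2-fold moved on the FPKM scale, where the pseudocount shrinks folds. With the filter fewer genes were tested, but on log2(FPKM + 1) values this did not change these counts. They were 377 higher and 402 lower on log2(FPKM + 1) values with or without the filter, and 604 higher and 778 lower on log2(FPKM + 0.1), against 940 and 1204. Leaving out 1 library at a time gave 3969 to 4215 genes higher, 3901 to 4170 lower, 913 to 999 at least 2-fold higher, 1160 to 1279 at least 2-fold lower, an Nps log2 fold change of 13.62 to 15.41, 8 to 10 lists passing camera, and a median of the PI3K list of -0.08 to 0.03. Over all alternatives the Nps log2 fold change was 12.65 to 15.98. Of the 31 lists, 9 passed camera with the preset correlation, 0 with the estimated correlation (3 at an unadjusted p under 0.05) and 23 with fry, which tests another question. The 0 does not by itself show that correlation between genes undid the calls, since that setting also has fewer degrees of freedom. The smooth muscle, neurotrophic factor and p53 lists had estimated correlations of -0.0125, -0.0161 and 0.00378, below the preset 0.01. All other lists that passed lay well above it, from 0.101 for the unfolded protein and integrated stress responses to 0.382 for the cell cycle. If those estimates hold, the preset made the camera p-values of these lists too small. Of the 9, the list of the unfolded protein and integrated stress responses passed under 9 of the 12 remaining alternatives and each of the others under all 12. The PI3K list (median -0.0125) passed with fry (adjusted p = 0.00489) and with no other alternative, where its adjusted p was 0.630 to 0.972. Among the 100 genes taken by the naming rule besides Nps, 1696 values were recomputed and 1692 kept their direction and side of the threshold. The other 4 belong to Erg, which passed with upper-quartile factors, no filter, the stricter filter and without EMSC replicate 3, and the cause was not tested. With the replicate block, 4331 genes were higher and 4257 lower, 937 and 1175 of them at least 2-fold, Nps had a log2 fold change of 14.03, 9 lists passed and the PI3K median was -0.0107. Libraries of the same number did not deviate together (correlations of deviations across genes -0.0389, 0.0460 and 0.0356), and not every library correlated best with its own number. At this depth, changes of 1.2-fold were recovered in 54% of simulated cases, all in genes with a mean of at least 1 CPM, so differences of that size can be missed. Few simulated genes carried a change, whereas 8600 of 14505 genes passed in the real comparison. The adjusted threshold was therefore stricter in the simulation, and the 54% need not hold for the real comparison.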

Other observations

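The tests of 1 culture per group, of skeletal muscle cells and of the smooth muscle genes that were low in EMSC were chosen after the result was seen. Early response genes moved in both directions. Of 26 tested cAMP and calcium response genes, 14 rose and 11 fell, the same adjusted over the list alone (median 0.32, camera adjusted p = 0.352). Btg2, an antiproliferative gene, rose 2.08-fold and the Krüppel-like factor gene Klf4 fell from 138 ± 4.10 to 41.8 ± 2.21 CPM (SD, n = 3). Chosen after their values were seen, the orphan nuclear receptor genes Nr4a1, Nr4a2 and Nr4a3 rose, with log2 fold changes of 1.60, 1.44 and 3.82, and Rgs2, a regulator of G protein signalling, rose by 3.01, while Fos, Egr1 and Egr2 fell, with log2 fold changes of -1.06, -0.64 and -1.58. Of 43 tested receptor tyrosine kinase and ligand genes, 17 rose and 14 fell, or 18 and 14 adjusted over the list alone. Igf2, insulin-like growth factor 2, fell from 1079 ± 47.7 to 271 ± 5.42 CPM and Pdgfc fell 3.28-fold. That list had a median of 0.06 and a mean of -0.06, and camera pointed upward at adjusted p = 0.683. Inflammatory genes were balanced at 9 higher and 9 lower of 23 tested, the same adjusted over the list alone (median -0.21, camera adjusted p = 0.684), with the complement gene C3 down from 1766 ± 110 to 276 ± 8.77 CPM and the superoxide dismutase gene Sod2 up 1.82-fold. Of 33 tested interferon-stimulated genes, 19 rose and 8 fell, the same adjusted over the list alone (median 0.35, camera adjusted p = 0.250). Their 2 members with the smallest p were Gbp2, which fell 2.14-fold, and the peptide transporter gene Tap1, which rose 1.91-fold.

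Lineage genes changed without a common direction. Of 11 tested chondrogenic genes, 2 rose and 7 fell (median -0.68, camera adjusted p = 0.491), with Comp among the largest decreases of all genes and Acan, aggrecan, up from 2.07 ± 0.217 to 18.7 ± 1.28 CPM (SD, n = 3). Of 9 osteogenic genes, 4 rose and 4 fell (median -0.32, mean 0.23, camera upward with adjusted p = 0.684). Tnfrsf11b, osteoprotegerin, rose 5.06-fold to 618 ± 43.8 CPM and Runx2, the osteoblast transcription factor gene, fell 1.47-fold. Among 9 adipogenic genes 2 rose and 4 fell (median -0.06, camera adjusted p = 0.683), with Cebpb up 1.53-fold and Cebpa down 1.76-fold. Neural crest and progenitor genes rose in 5 and fell in 8 of 16 (median -0.42, camera adjusted p = 0.319), with Tfap2a up 2.49-fold and Snai1 down 2.41-fold. Of 11 neuronal genes, 3 rose and 4 fell (median -0.32, camera adjusted p = 0.607), with Stmn2, a growth cone protein gene, down 4.03-fold and Eno2 up 1.41-fold. Apoptosis regulators rose in 7 and fell in 4 of 18 (median 0.06, camera adjusted p = 0.574). The p53 target Pmaip1 rose 2.20-fold and Bcl2l1 1.63-fold. Cholesterol synthesis genes rose in 8 and fell in 12 of 23 (median -0.14, camera adjusted p = 0.372), with Sc5d up 1.77-fold and Sqle down 1.77-fold. In these 7 lists the counts adjusted over the list alone were the same.

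More than 1 gene in 2 differed between the groups. Gene length was not the whole cause: 92.9% of the calls kept their sign and passed after each library's trend on gene length was removed. With all libraries thinned to 39082245 reads, 99.3% of the calls did so. The largest total was only 40261205 reads, so thinning could change little and is no real test of depth. The near-equal totals themselves left little difference in depth to act. Only 10 splits of the 6 libraries exist, too few for a share under 0.05. With edgeR, 1 of the 10 splits, the real one, called 8600 genes, and the highest other split called 0, with 48 to 150 genes at an unadjusted p under 0.05 in the other 9 splits. Each of those 9 splits places libraries of both groups on either side, so the difference between the groups enters its spread. Few calls were bound to follow, and the 0 does not measure how many calls chance would give. The coefficient of variation of 0.0737 leaves open that each group may be 1 culture sequenced 3 times, in which case differences between any 2 cultures would pass alongside an effect of neuropeptide S, and the design does not separate these.

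The rise of contractile genes reached Pln and Casq2, the calsequestrin gene, which was chosen after its values were seen and rose from 0.689 ± 0.234 to 30.6 ± 0.816 CPM (SD, n = 3). Skeletal muscle fibres as an admixture would bring creatine kinase and skeletal actin at or above that level. In NPS-EMSC the median of the 11 skeletal muscle genes was 0.0352 times the mean of Pln and Casq2, with Ckm, named after its values were seen, at 0.0861 ± 0.0293 CPM and Acta1 at 6.05 ± 0.527 CPM, which argues against fibres as the source of Pln and Casq2. Acta1 and Myh3 did rise, and immature muscle cells were not tested. Smooth muscle cells could not be excluded: a second list of smooth muscle genes, written before its values were seen, had 19 of 25 tested members higher, 3 lower (Fhl1, Mustn1 and Tes, named after their values were seen) and a median log2 fold change of 0.74 (SE 0.12). This met neither the share of 0.8 higher nor the median of 1 set for such cells, and by the median alone smooth muscle cells would have been excluded. However, the median member stood at 49.8 CPM in EMSC, above the mean of 32.1 CPM of Pln and Casq2 in NPS-EMSC, and genes at such levels can hide a small share of added cells. This reason was added after the median was seen. Of the 11 members under 32.1 CPM in EMSC, 7 rose and 2 fell, and their median of 0.84 (SE 0.41) lay within its SE of the bound of 1, so they decide nothing either way. The SE of a list median was obtained by resampling the member genes as if they were independent. It holds no spread between libraries. Whether the cells themselves moved towards a myofibroblast state, as a hypothesis, or smooth muscle cells were selected in culture stays open, with Des at 0.802 CPM and the smooth muscle regulator gene Myocd, chosen from the second list after its values were seen, up from 4.33 to 20.3 CPM (log2 fold change 2.22, SE 0.13).

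The fall of leukocyte genes may reflect fewer macrophages among the NPS-EMSC cells. In a second list of 35 leukocyte genes, written before its values were seen, 19 of 23 tested members had a negative log2 fold change, 17 of them called. The median was -1.36 (SE 0.32, from resampled members), past the bound of -1 set for this explanation. The members named here were chosen after their values were seen. The macrophage receptor gene Mrc1 fell from 8.18 to 1.16 CPM (log2 fold change -2.77, SE 0.20), and the cathepsin gene Ctss fell from 8.07 to 3.44 CPM (log2 fold change -1.22, SE 0.18). Against it, Fgr and Pik3ap1 rose, and the 2 most abundant members changed less or did not pass: Arhgdib fell from 15.9 to 10.5 CPM (log2 fold change -0.59, SE 0.12), and Cd48 stood at 78.6 CPM in EMSC and 85.4 CPM in NPS-EMSC (log2 fold change 0.12, SE 0.05, adjusted p = 0.0508). Bulk libraries do not separate a loss of cells from a loss of these transcripts within cells.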
